A study of Mus musculus with 49 samples.

How the data were processed

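RNA sequencing was measured in hippocampus, the brain region of spatial and episodic memory, from 49 mice of the inbred strain C57BLKS/J at 3 months of age, 1 library per mouse according to the series' design text. The labels place the libraries in 6 groups named by codes: CD-C, CD-F, FD-C, FFD-C and HFD-F with 8 libraries each and HFD-C with 9. By the series title, which speaks of maternal obesity, offspring and a diet high in fibre, the part of the code before the hyphen was read as the diet of the dam and the letter after it as the diet of the offspring. The labels do not spell the codes out, and the codes are used throughout. Each sample title also carries an XX or XY mark, with 4 XX libraries in each group, and a prefix such as HFD2.2. There are 20 such title prefixes. They may mark litters or dams, which no label states, and 3 of them hold libraries of both HFD-C and HFD-F, while CD-C and CD-F share none.

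The authors deposited a single table of FPKM (length- and depth-scaled fragment counts), with 42521 rows and a column for every library. Libraries followed the BGI-500 workflow after phenol-chloroform extraction, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.38, HISAT2, StringTie 1.3.4d and the mouse genome build GRCm38.p6, without giving their roles or settings. Of the rows, 23263 carry an assembled identifier of the kind StringTie writes, 1146 name more than 1 gene, and 1693 symbols stand on more than 1 row, so that reads of a single gene can be spread over rows. Columns summed to between 1220340 and 1340551 FPKM. Read totals are not given in the sources used here. The spacing of low values over 1719 genes gave relative depths between 0.913 and 1.05, but this compares only values near a common spacing, so that larger differences in depth would not show, and no absolute depth or counting error can be given. Neither the strand setting nor the annotation behind the assembled rows is given in the sources used here, and values of genes on several rows, of near-identical copies and of overlapping or antisense genes are therefore uncertain.

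Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 0.5) for the 16029 rows with a mean of at least 0.5 FPKM. All 49 libraries entered a single model with a term per group and the XX or XY mark. Tests were two-sided with Benjamini-Hochberg adjustment over the rows tested in a comparison, and adjusted p under 0.05 was the threshold. Fold changes are differences on that log2 scale, which understates the change of low genes, and SE is the limma standard error. Group levels are means ± SD of FPKM. Comparisons were the maternal code (HFD-C, FD-C and FFD-C against CD-C, and FFD-C against HFD-C), the offspring code (CD-F against CD-C, HFD-F against HFD-C), HFD-F against CD-C, 2 interactions between codes, XX against XY, and the interaction of that mark with HFD-C against CD-C. Comparisons that share libraries also share their chance values. For the question whether FFD-C or HFD-F differ from HFD-C in the direction opposite to that of HFD-C from CD-C, HFD-C was divided at random 100 times so that no library stood on both sides, beside 100 simulated draws without any effect.

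Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for lists with at least 5 tested members. There were 45 lists. The cell type and region lists were pan-neuronal, dentate granule cell, CA1 pyramidal cell, CA2 and CA3 pyramidal cell, GABAergic interneuron, astrocyte, homeostatic microglia, oligodendrocyte and myelin, oligodendrocyte precursor, endothelial cell, pericyte and smooth muscle, fibroblast, choroid plexus, ependymal cell, blood, border macrophage, lymphocyte, striatum, thalamus, neocortex and hypothalamus. The functional lists were excitatory postsynapse, presynaptic release, GABA receptor, immediate early, neurotrophin and CREB, adult neurogenesis, oxytocin and dopamine, inflammation, complement, disease-associated microglia, interferon, MHC, short-chain fatty acid, glucocorticoid, circadian clock, insulin and leptin, cholesterol synthesis and SREBP targets, lipid oxidation, nuclear-encoded respiratory chain, mitochondrially encoded, cytosolic ribosomal protein, heat shock and unfolded protein, blood-brain barrier, and autism-associated genes. Blood and lymphocyte markers had 1 tested member each and the mitochondrially encoded list had 0, so 42 lists were tested.

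Named genes followed a fixed rule. In each of 5 main comparisons these were the 10 genes with the smallest p in either direction past the threshold, at a mean of at least 1 FPKM, without predicted, pseudogene or Y-linked names; where fewer than 5 passed in a direction, the 5 with the smallest p were taken and are given as not passing. Up to 4 passing members of each list and a panel of 17 synaptic, microglial, activity, choroid and fatty acid receptor genes were added. A few of the genes this rule names are left out of the text. The groups, the models, the lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives covered the pseudocount, the filter, scaling, quantile normalization, library weights, covariates, title prefixes, fewer libraries and each library left out. Alternatives chosen after the data were examined were removal of the trend with transcript GC, also with length, the 4 CD-C libraries with Alb transcripts or the libraries apart on the first principal component left out, Ttr as a covariate, means per prefix, and rows summed by symbol. Transcript GC came from GENCODE release 21 transcripts matched by symbol, with a value for 94.5% of tested rows. Coordinates are RefSeq gene positions on GRCm38.p6, matched by symbol. Tables and plots were made with the R package data.table (1.17.8), Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

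The test was checked on data simulated from the real means and spread, with 5 draws per comparison over 16029 rows. It recovered 50.8% of genes changed by 0.5 on the log2 scale and 83.8% of those changed by 1 for CD-F against CD-C, with 2.6 false calls on average, and 54.0% and 84.6% for HFD-C against CD-C, with 3.2 false calls. A GC trend in the direction of that of CD-F against CD-C was added equally to each simulated CD-F library, over 15154 rows. It gave 176.7 false calls on average, and 3 after its removal. The added trend was weaker than the measured difference in mean GC slope between CD-F (0.159) and CD-C (-0.0739). The measured trend also differed widely between CD-F libraries, so 176.7 does not estimate how many real calls follow GC. Within a title prefix the residual correlation over genes was 0.0356.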

Results

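Hippocampal RNA was sequenced from 49 mice in 6 groups, with 8 libraries in CD-C, CD-F, FD-C, FFD-C and HFD-F and 9 in HFD-C. Expression was read as FPKM, and 16029 rows of the table passed the filter on mean level. Columns summed to 1253810 to 1282829 FPKM in CD-C, 1258269 to 1340551 in CD-F, 1220340 to 1336276 in FD-C, 1222660 to 1299228 in FFD-C, 1245489 to 1288304 in HFD-C and 1248488 to 1316129 in HFD-F. Sequencing depth is unknown, and a limited estimate of relative depth from low values lay between 0.913 and 1.05. The series title frames the study as maternal obesity, offspring behaviour and a high-fibre diet. The comparisons therefore ask how hippocampal expression differs with the maternal code and with the offspring code.

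The XX and XY marks in the sample titles matched the sex-linked genes. Xist, the RNA that silences an X chromosome, was higher in XX libraries by 7.38 (SE 0.132) on the log2 scale. The Y-linked genes Eif2s3y (-9.64, SE 0.137), Kdm5d (-5.44, SE 0.076), Ddx3y (-5.33, SE 0.111) and Uty (-2.85, SE 0.068) were lower. The X-linked genes Eif2s3x (0.54), Kdm6a (0.52) and Ddx3x (0.36) were also higher in XX. Kdm5c (0.32, adjusted p = 0.0626 with limma) did not pass. Outside the sex chromosomes, the immune gene Gbp3 (0.74, SE 0.136), B2m (0.34, SE 0.068), which encodes the light chain of MHC class I, and Tmem252 (0.88, SE 0.181) were higher in XX. So was H2-Q4 (0.52, SE 0.108), an MHC class I gene on 4 rows and hence uncertain. Tiparp (0.30, adjusted p = 0.052) did not pass. Across all groups 18 genes passed, 14 higher and 4 lower in XX. Between HFD-C and CD-C, limma found 0 genes whose difference depended on the mark, with 214 at an unadjusted p under 0.05. Independent genes without an effect would give 801. Marks regrouped at random within groups gave a median of 313, and 92 of 100 regroupings, the real one included, reached 214.

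HFD-C against CD-C asks what the maternal code HFD does to offspring on code C. No single gene passed in this comparison of 9 with 8 libraries. The genes nearest to the threshold were lower in HFD-C and are known as liver products: Alb, Ahsg, Serpina3k, Serpina1d (on 2 rows) and Mup13 (on 3 rows), with adjusted p between 0.0744 and 0.0748. Their transcripts were high in 4 of the 8 CD-C libraries, at 24.3 to 50.1 FPKM for Alb, 14.4 to 40 for Ahsg, 15.2 to 28.5 for Serpina3k, 18.3 to 20.2 for Serpina1d and 13.4 to 17.5 for Mup13. In the other 45 libraries the highest values were 0.945 FPKM for Ahsg, 0.285 for Mup13, 0.145 for Alb, 0.0418 for Serpina1d and 0 for Serpina3k. Alb was listed at 0 in the other 4 of CD-C. Of the genes higher in HFD-C, Tbc1d25 had 160 ± 19 against 119 ± 52.7 FPKM (log2 0.57, SE 0.168), Grip1, a scaffold of glutamate receptors, 2.93 ± 0.391 against 2.08 ± 0.489 (0.42, SE 0.125), and Nhsl2 26.1 ± 12.9 against 13.8 ± 3.93 (0.79, SE 0.268). The GABA-B receptor subunit Gabbr1 (0.99, SE 0.310; 4 rows) and the lysosomal cystine transporter Ctns (2.69, SE 0.812; 2 rows) share their symbols with other rows and are uncertain. None of these 5 passed (adjusted p = 1). The row of Tbc1d25 takes 2 separate levels, and the 3 libraries at the lower level are all of CD-C.

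With limma, 0 genes passed in HFD-C against CD-C, and 379 had an unadjusted p under 0.05. Independent genes without an effect would give 801, but genes are not independent. Random regroupings of these libraries gave a median of 284, and 21 of 100, the real grouping included, reached 379. Of the panel genes, the growth factor Bdnf stood at 41.3 ± 9.91 against 42.3 ± 6.06 FPKM, the postsynaptic scaffold Dlg4 (2 rows) at 451 ± 47.4 against 456 ± 38.9, and the vesicle protein Syp at 789 ± 87.3 against 786 ± 60.4. Of microglial genes, the receptor Csf1r stood at 804 ± 109 against 777 ± 91.2, P2ry12 at 44.6 ± 15.6 against 42.7 ± 5.99, and Tmem119 at 4.64 ± 0.544 against 5.09 ± 0.939. Log2 differences of the others were -0.59 (SE 0.530) for Cx3cr1, 0.05 (SE 0.211) for Aif1 on 4 rows, 0.58 (SE 0.666) for Trem2 on 2 rows, 0.22 (SE 0.217) for the oxytocin receptor Oxtr, -0.01 (SE 0.214) for Fos, 0.14 (SE 0.233) for Arc and -1.40 (SE 1.57) for the choroid plexus product Ttr. Each had an adjusted p of 1. The cytokines Tnf and Il1b and the fatty acid receptors Ffar2 and Ffar3 were below the filter and were not tested.

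Among the lists, 11 of 42 passed the preset correlation in HFD-C against CD-C, although no member passed over all genes. Lower in HFD-C were heat shock and unfolded protein genes (median log2 -0.18 over 20 members, adjusted p = 8.82e-06), fibroblast (-0.47 over 11, 0.000119), border macrophage (-0.56 over 5, 0.000452), ribosomal protein (-0.11 over 29, 0.00159), dentate granule cell (-0.24 over 12, 0.00812), choroid plexus (-0.62 over 13, 0.00812) and respiratory chain genes (-0.06 over 31, 0.0349). Higher were SREBP targets (0.08 over 23, 0.00319), autism-associated genes (0.07 over 22, 0.00846), presynaptic release (0.06 over 25, 0.0349) and GABA receptor genes (0.07 over 16, 0.0349). Of the last, 1 member passed adjusted over the list alone. None held with an estimated correlation: border macrophage had an adjusted p = 0.879 with an estimated correlation, and the other 10 an adjusted p = 0.985 with an estimated correlation. Across genes the difference between HFD-C and CD-C followed transcript GC and length (Spearman -0.274 and 0.323 over 13761 genes), and genes are not independent replicates. Leaving out CD-C library 1, 3, 4 or 6, each without Alb, gave 5 genes.

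FFD-C against HFD-C sets another maternal code against HFD with the offspring code held at C. The clock-related ubiquitin ligase gene Fbxl21 had the smallest p, at 2.21 ± 0.465 FPKM in FFD-C (n = 8) and 3.80 ± 0.829 in HFD-C (n = 9; log2 -0.66, SE 0.142, adjusted p = 0.482 with limma). Lower values were also seen for the neuronal transcription factor Myt1l (125 ± 31.1 against 175 ± 24.6 FPKM), the microtubule protein Camsap2 (98.5 ± 23.4 against 135 ± 11), Naa30 (7.78 ± 1.1 against 10.1 ± 0.688) and the combined row of Acsl3 and Utp14b (5.10 ± 1.29 against 7.95 ± 2.09). Higher values were seen for Cyp2d22 (386 ± 67.7 against 257 ± 56.1), the transcription kinase Cdk9 (241 ± 28.2 against 206 ± 22.9), Lin37 (19.2 ± 2.17 against 15.8 ± 0.940), Plp2 (70.2 ± 19.9 against 50.8 ± 9.07) and Pgm2l1 (734 ± 337 against 268 ± 260). None passed: apart from Fbxl21, these had an adjusted p of 0.761. Panel genes did not pass either, with log2 -0.03 (SE 0.153) for Bdnf, 0.05 (SE 0.081) for Dlg4, 0.09 (SE 0.091) for Syp, 0.28 (SE 0.530) for Cx3cr1, -0.04 (SE 0.097) for Csf1r and 0.88 (SE 0.666) for Trem2. Limma called 0 genes, with 956 at an unadjusted p under 0.05, where independent genes without an effect would give 801. Random regroupings of these libraries gave a median of 560, and 19 of 100, the real grouping included, reached 956.

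Ribosomal protein (median log2 0.18 over 29, adjusted p = 3.71e-07) and respiratory chain genes (0.13 over 31, 0.0034) lay higher in FFD-C than in HFD-C at the preset correlation, with 0 members called. Autism-associated genes (-0.13 over 22, 0.00232; 1 member lower adjusted over the list alone), the excitatory postsynapse (-0.16 over 25, 0.00755; 1 lower adjusted over the list alone) and GABA receptor genes (-0.15 over 16, 0.00833; 0 adjusted over the list alone) lay lower. All 5 had an adjusted p = 0.995 with an estimated correlation. Across genes the difference followed transcript GC and length (Spearman 0.393 and -0.453 over 13761 genes), and genes are not independent replicates.

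Whether FFD-C or HFD-F moved hippocampal expression back from HFD-C towards CD-C was examined across all 16029 genes. The change of FFD-C from HFD-C and that of HFD-C from CD-C correlated at -0.452, but the shared HFD-C libraries alone gave -0.481 in simulated draws without an effect, and the covariance was -0.0240 against -0.0287. With HFD-C split so that no library was used on both sides, the correlation was -0.011 (covariance -0.00075), within the range of -0.284 to 0.175 without an effect, and 45 of 100 draws were as low. For HFD-F the unsplit value was -0.292 (covariance -0.0172 against -0.0290) and the split value 0.071 (covariance 0.00605), within -0.231 to 0.277, with 81 of 100 draws as low. Over the 1916 genes with any difference among the groups the split values were -0.187 for FFD-C and 0.107 for HFD-F. Draws without an effect, with as many genes chosen by the same F-test, ran from -0.676 to 0.298 and from -0.549 to 0.239, with 57 and 98 of 100 as low. No opposite movement beyond that of such draws was therefore measured for either group. Limma called 0 genes in HFD-C against CD-C and the ranges without an effect are wide, so an opposite movement is not excluded either.

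FD-C against CD-C compares another maternal code under offspring code C. Of the genes lower in FD-C, the adaptor Nck1 stood at 2.40 ± 0.599 against 3.50 ± 0.264 FPKM (n = 8 each; log2 -0.49, SE 0.093, adjusted p = 0.0187) and the protein kinase A inhibitor Pkia at 54.6 ± 5.13 against 71.6 ± 5.49 (-0.39, SE 0.082, 0.0284). The ribosome biogenesis gene Wdr3 (-0.29, SE 0.055), the coenzyme Q carrier Coq10b (-0.40, SE 0.080), the secreted factor Fam3c (-0.34, SE 0.072) and the ether lipid enzyme Agmo (-0.46, SE 0.098) fell as well, in 7 or 8 of the 8 FD-C libraries. The liver genes Serpina3k, Serpina1d and Mup13 passed too, being listed at 0 in FD-C and present in the 4 CD-C libraries already described. Genes nearest to passing in the other direction were Tbc1d25 (178 ± 20.8 against 119 ± 52.7 FPKM; 0.73, SE 0.172, adjusted p = 0.0579; low in 3 CD-C libraries, as described), the polyamine oxidase Smox (48.1 ± 2.66 against 37.4 ± 3.51; 0.0953), Gga1 (84.8 ± 4.22 against 73.9 ± 4.65; 0.115) and Fgf1 (91.3 ± 15.6 against 66.4 ± 12.8; 0.123).

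In all, limma called 32 genes in FD-C against CD-C, 1 higher and 31 lower, and 1529 had an unadjusted p under 0.05. Of the lists, dentate granule cell (median log2 -0.37 over 12, adjusted p = 0.0323; 1 member lower adjusted over the list alone) and respiratory chain genes (-0.12 over 31, 0.0393; 1 lower adjusted over the list alone) lay lower at the preset correlation. Oligodendrocyte precursor (0.14 over 10, 0.0323), ependymal (0.40 over 8, 0.0427) and presynaptic genes (0.09 over 25, 0.0476) lay higher, with 0 members called. All 5 had an adjusted p = 0.999 with an estimated correlation. The genes that fell had a median transcript GC of 42.7%, and 0 passed with the GC trend of each library removed. The count depended on single libraries and stood at 1 without FD-C library 3 and 77 without FD-C library 5. It was 16, 7, 13, 13, 7, 2 and 9 without CD-C libraries 1, 2, 3, 4, 5, 7 and 8, and 8, 20, 7, 3, 5 and 20 without FD-C libraries 1, 2, 4, 6, 7 and 8. It was 1 without the 4 CD-C libraries that held Alb, 1 with the groups compared alone, 13 with a random prefix block and 0 with means per title prefix.

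CD-F against CD-C compares offspring code F with C under maternal code CD, and it held the largest number of changed genes of the comparisons made. Of the higher genes, the lipogenic transcription factor Srebf1 stood at 37.6 ± 5.83 FPKM in CD-F and 24.3 ± 3.03 in CD-C (n = 8 each; log2 0.62, SE 0.102, adjusted p = 8.51e-05). The cholesterol synthesis gene Dhcr7 stood at 7.06 ± 0.788 against 5.52 ± 0.557 (0.33, SE 0.077, 0.00308). Of the lower genes, the endoplasmic reticulum chaperone Hspa5 stood at 135 ± 24.3 against 251 ± 60.6 FPKM (-0.88, SE 0.179, 0.000825), the cytosolic chaperone Hsp90aa1 at 210 ± 80.6 against 361 ± 31.3 (-0.87, SE 0.173, 0.00071) and Hsp90b1 at 32.0 ± 11.1 against 49.9 ± 5.67 (-0.71, SE 0.140, 0.000678). The topoisomerase Top1 (51.8 ± 17.3 against 95.5 ± 9.20 FPKM) and the cap-binding subunit Ncbp2 (25.8 ± 2.67 against 36.8 ± 1.55) fell as well. On GRCm38.p6, Srebf1 lies on chromosome 11 at 60199084 to 60224186, Hspa5 on chromosome 2 at 34772090 to 34776529 and Ncbp2 on chromosome 16 at 31948546 to 31958472.

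The 10 genes with the smallest p among those higher in CD-F were, by fold, the actin regulator Wasf2 (log2 0.81, SE 0.158), Srebf1, the focal adhesion protein Zyx (0.53, SE 0.099), the lysosomal or reticulum genes Cln6 (0.50, SE 0.099) and Man2b2 (0.48, SE 0.087), the pyruvate carboxylase gene Pcx (0.46, SE 0.082), the telomere gene Ctc1 (0.42, SE 0.074), the phosphate carrier Slc20a2 (0.39, SE 0.076), the ubiquitin ligase Wwp2 (0.39, SE 0.077) and the citric acid cycle enzyme Ogdh (0.36, SE 0.068). Among those lower they were Top1 (-0.94, SE 0.133), the Hsp90 co-chaperone Ptges3 (-0.67, SE 0.089), Nck1 (-0.67, SE 0.093), Pnrc2 (-0.65, SE 0.076), Fam133b (-0.56, SE 0.080), the checkpoint gene Rad17 (-0.53, SE 0.074), Bfar (-0.53, SE 0.066), Tmem263 (-0.52, SE 0.070), Ncbp2 (-0.51, SE 0.062) and the GTPase Rap1b (-0.45, SE 0.064). Adjusted p ran from 9.78e-07 for Pnrc2 to 0.00071 for Cln6, and each of the 20 genes differed in the same direction in 8 of 8 CD-F libraries from the mean of CD-C.

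**Figure D1:**
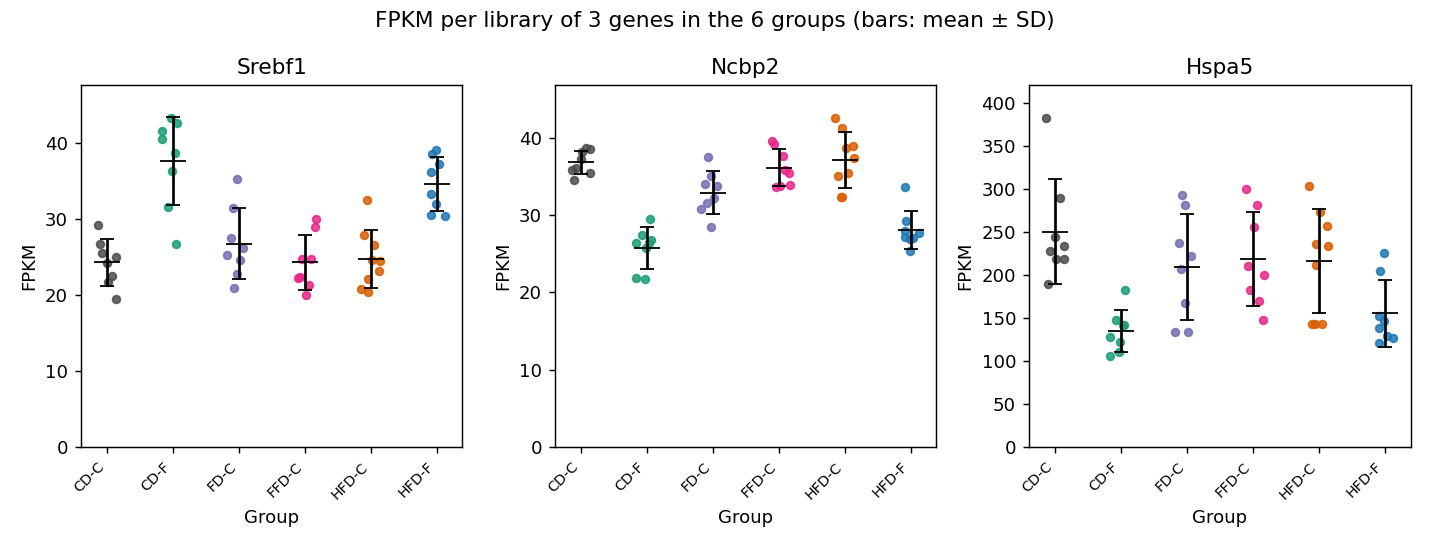
FPKM of Srebf1, Ncbp2 and Hspa5 (y axes, linear from 0) in each library of the 6 groups (x axes), with points for libraries and bars for mean ± SD. Srebf1 means were 37.6 in CD-F and 34.6 in HFD-F and between 24.3 and 26.7 in the groups with offspring code C, and Ncbp2 means were 25.8 and 28.1 against 32.9 to 37.1.

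Of 23 measured genes of cholesterol synthesis and SREBP targets, 12 rose and 0 fell in CD-F against CD-C (13 and 1 adjusted over the list alone), Dhcr7 among them. The median was 0.30, with an adjusted p = 1.57e-06 at the preset correlation and an adjusted p = 0.929 with an estimated correlation. Of 20 heat shock and unfolded protein genes, 11 fell and 0 rose (11 and 1 adjusted over the list alone), including the chaperone Creld2 (-0.65, SE 0.141). Their median was -0.46 (adjusted p = 3.72e-07, and adjusted p = 0.929 with an estimated correlation). With the GC trend of each library removed, Srebf1 (0.49), Hspa5 (-0.77), Hsp90aa1 (-0.68) and Creld2 (-0.76) still passed, and 9 members of the former list rose and 12 of the latter fell.

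In the deposited values synaptic genes went both ways. Over all 16029 rows 728 were called higher and 1423 lower in CD-F against CD-C, and member counts near these shares are no result about a list. Of 25 presynaptic genes, 5 rose in CD-F (5 adjusted over the list alone), with the vesicle fission gene Dnm1 (0.40, SE 0.120), Cplx1 (0.35, SE 0.115) and Syn1 (0.29, SE 0.093) as examples. The list median was 0.23 (adjusted p = 0.0204 at the preset correlation, adjusted p = 0.987 with an estimated correlation). Of 25 excitatory postsynaptic genes 2 rose, with the NMDA receptor subunit Grin1 (0.33, SE 0.105) among them. In the same list 4 fell, with the AMPA receptor subunit Gria2 (-0.72, SE 0.18) and the glutamate receptor Grm5 (-0.57, SE 0.162) among them. Of 16 GABA receptor genes 3 fell, with Gabra2 (-0.91, SE 0.259) and Gabrb2 (-0.69, SE 0.209) among them, and Gabbr1 on 4 rows rose (0.91, SE 0.319). Adjusted over the list alone 4 fell and 1 rose. Of 22 autism-associated genes 2 rose, with Tsc2 (0.26) among them, and 4 fell, with Fmr1 (-0.60, SE 0.131) among them. Of 19 genes of neurotrophin and CREB signalling, Creb1 (-1.15, SE 0.345) and the calcineurin subunit Ppp3ca (-0.61, SE 0.148) fell and the receptor Ntrk2 rose (0.31, SE 0.101), with 3 lower and 1 higher adjusted over the list alone. Of 22 immediate early genes Egr1 rose (0.72, SE 0.249) and Klf4 fell (-0.45, SE 0.145), with 4 higher and 2 lower adjusted over the list alone. The neurogenesis genes Sox11 (-0.78, SE 0.152), Neurod1 (-0.51, SE 0.174) and Sox4 (-0.36, SE 0.104) fell, 3 of 15 by either count. Most of these calls ended with the GC trend removed. Then 0 presynaptic genes were called, 1 excitatory postsynaptic and 1 GABA receptor gene were higher, and 0 of either list were lower. Of the genes named here, Fmr1 (-0.20), Ppp3ca (-0.49), Ntrk2 (0.32), Klf4 (-0.55), Sox11 (-0.70) and Sox4 (-0.41) still passed.

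In the deposited values, members of glial and vascular lists that were called in CD-F mostly rose. None of these lists passed at the preset correlation, where 3 of 42 did: SREBP targets, heat shock and presynaptic genes. Of 20 homeostatic microglia genes 3 rose, by either count: Csf1r (1040 ± 139 against 777 ± 91.2 FPKM; 0.42, SE 0.1), Sall1 (0.53, SE 0.129) and Itgam (0.50, SE 0.153). Of 18 complement and engulfment genes 5 rose (6 adjusted over the list alone, where 2 fell), such as the lysosomal Cd68 (0.54, SE 0.118), Sirpa (0.24, SE 0.062) and Cx3cl1 (0.27, SE 0.089). In the inflammation list Cd68 rose, while the NF-kappaB inhibitor Nfkbia (-0.53, SE 0.128) and Lcn2 (-2.09, SE 0.715) fell, 1 and 2 of 8, with 1 and 3 adjusted over the list alone. Ctsb (0.23, SE 0.062) was the member of the disease-associated microglia list that rose, 1 of 11, with 4 adjusted over the list alone. Oligodendrocyte precursor genes Cspg5 (0.63, SE 0.161), Sox10 (0.52, SE 0.181) and Cspg4 (0.37, SE 0.103) rose, 3 of 10 by either count. So did the myelin gene Gjb1 (0.82, SE 0.287), 1 of 16 and 0 adjusted over the list alone, and the astrocyte gene Aldh1l1 (0.33, SE 0.104), 1 of 11 by either count. Endothelial Kdr (0.62, SE 0.204) and Cdh5 (0.44, SE 0.153) rose, 2 of 10, and so did the pericyte genes Notch3 (0.56, SE 0.148) and Pdgfrb (0.54, SE 0.146), 2 of 8, both by either count. In the blood-brain barrier list Cdh5 was among the 2 of 13 that rose, with 2 higher and 2 lower adjusted over the list alone. With the GC trend removed, 0 genes of the endothelial, pericyte, astrocyte and myelin lists were called. Of the genes named here, Csf1r (0.31), Sall1 (0.47), Itgam (0.50), Cd68 (0.46), Nfkbia (-0.62), Ctsb (0.22) and Cspg5 (0.57) still passed.

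Of metabolic genes in CD-F against CD-C, the histone deacetylase Hdac2 fell (-0.41, SE 0.071) and the acetate-activating enzyme Acss2 rose (0.26, SE 0.059), 1 of 10 each way in the short-chain fatty acid list. Of 20 lipid oxidation genes Hadha (0.25, SE 0.071) and Cpt1c (0.22, SE 0.076) rose and Oxct1 (-0.20, SE 0.055) and Fabp7 (-0.58, SE 0.195) fell, with 3 higher and 2 lower adjusted over the list alone. Of 19 insulin and leptin genes Pik3ca (-0.44, SE 0.097) and Igf1 (-0.45, SE 0.151) fell and Akt2 (0.34, SE 0.116) rose. Tsc22d3 (-0.54, SE 0.167) and Lcn2 fell among 19 glucocorticoid response genes, with 1 lower adjusted over the list alone. The clock gene Nr1d2 (-0.40, SE 0.125), 1 of 17, and the interferon-induced Iigp1 (-0.82, SE 0.247), 1 of 19, fell by either count. Among respiratory chain genes Uqcrb (-0.49, SE 0.131), Cox7b (-0.45, SE 0.136) and Ndufa5 (-0.44, SE 0.146) fell, 3 of 31, and among ribosomal protein genes Rpl7 (-0.40, SE 0.132) and Rpl5 (-0.38, SE 0.121), 2 of 29 and 0 adjusted over the list alone. Such counts are near the share over all rows, where 1423 of 16029 were called lower. With the GC trend removed, only Acss2 (0.19) of the genes named here still passed, and Igf1 stood at 0.001.

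In the cell type and region lists, the dentate granule cell gene C1ql3 (-0.66, SE 0.143), 1 of 12, and Pdp1 (-0.43, SE 0.135) of the thalamus list, 1 of 12, fell by either count. Limma called 0 members over all genes and 0 adjusted over the list alone among pan-neuronal (9 tested), CA1 (9), CA2 and CA3 (12), GABAergic interneuron (12), fibroblast (11), choroid plexus (13), ependymal (8), border macrophage (5), striatum (12), neocortex (13), hypothalamus (7), MHC (12) and oxytocin and dopamine genes (10). Medians ranged from -0.09 for pan-neuronal to 0.46 for choroid plexus genes, and the choroid plexus product Ttr ran from 274 to 13300 FPKM in the 4 CD-C libraries with Alb and from 6.07 to 18800 in the other 45. With the GC trend removed, 0 genes of the thalamus list were called, so Pdp1 no longer passed. Called then were 1 dentate granule cell and 1 pan-neuronal gene, both lower, and 1 oxytocin and dopamine gene, higher.

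Altogether limma called 2151 genes in CD-F against CD-C, 728 higher and 1423 lower, with 4302 at an unadjusted p under 0.05. The changes followed transcript GC (Spearman 0.525 over 13761 genes, which are not independent replicates), and the median GC was 55.0% in the genes that rose and 42.4% in those that fell. The trend was uneven: GC slopes of single libraries, on a common log2 scale, ran from -0.0945 to 0.494 in CD-F and from -0.136 to -0.0247 in CD-C. Without CD-F replicate 1 (slope 0.317) 1558 genes were called, without replicate 6 (-0.0945) 2596, and without replicate 8 (0.494, the steepest) 2197. Removing the GC trend of each library left 776 genes, 313 higher and 463 lower, and 594 of these were among the 2078 called before that have a GC value, all in the same direction. Without the 4 CD-C libraries that held Alb the count was 1234. With means per title prefix it was 881, with 104 higher and 777 lower. No title prefix holds libraries of both groups, and the rows of mitochondrial genes took 3.91 ± 1.32% of all FPKM in CD-F and 5.08 ± 0.55% in CD-C.

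**Figure D2:**
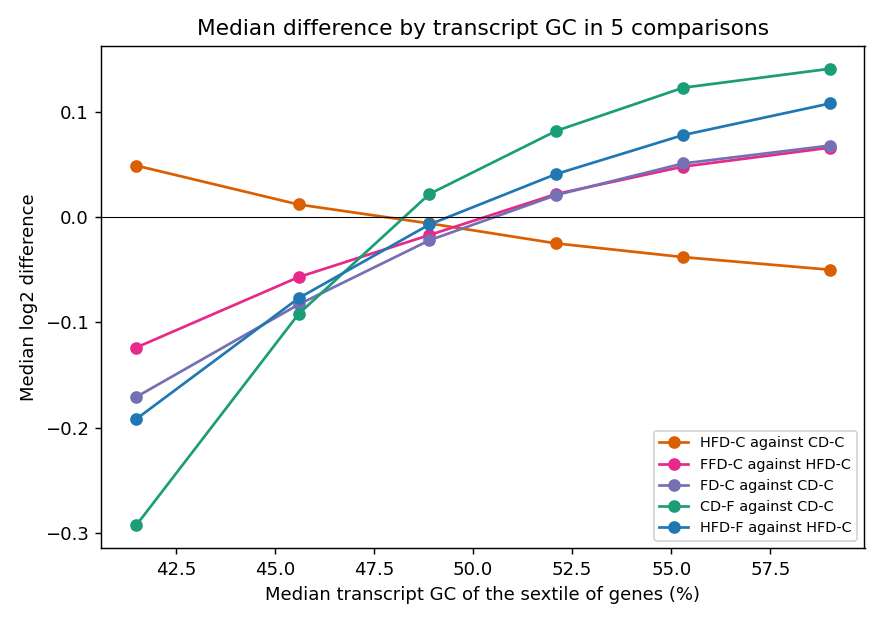
Median log2 difference (y axis) over sextiles of transcript GC in percent (x axis) for 5 comparisons, 1 line each. In CD-F against CD-C the medians ran from -0.293 in the lowest to 0.141 in the highest sextile, in HFD-F against HFD-C from -0.192 to 0.108, and in HFD-C against CD-C from 0.049 to -0.050.

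HFD-F against HFD-C asks for the effect of offspring code F under maternal code HFD. As in CD-F, Srebf1 was higher. It stood at 34.6 ± 3.53 FPKM in HFD-F (n = 8) and 24.7 ± 3.84 in HFD-C (n = 9; log2 0.49, SE 0.099, adjusted p = 0.00881). The fatty acid desaturase gene Fads2 stood at 246 ± 42.7 against 177 ± 19.5 (0.46, SE 0.1, 0.0143), and the mevalonate kinase gene Mvk at 15.6 ± 2.11 against 11.6 ± 2.33 (0.43, SE 0.1, 0.0205). Of the lower genes, Ncbp2 stood at 28.1 ± 2.46 against 37.1 ± 3.64 (-0.40, SE 0.060, 0.000788), Hnrnph2 at 161 ± 14.5 against 209 ± 15.9 (-0.37, SE 0.063, 0.00327). Hnrnpa1 stood at 50.8 ± 4.08 against 64.4 ± 5.10 (-0.34, SE 0.067, 0.008) and the poly(A)-binding protein partner Paip1 at 55.7 ± 4.57 against 67.5 ± 3.92 (-0.28, SE 0.055, 0.00857). The glucocorticoid-induced kinase Sgk1 fell from 604 ± 133 to 354 ± 142 FPKM (-0.85, SE 0.227, 0.0405).

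Also higher in HFD-F were the G protein subunit Gna12 (0.61, SE 0.126), the metalloprotease Mmp28 (0.61, SE 0.124), Lrrk1 (0.54, SE 0.127), Rab3il1 (0.45, SE 0.096), the phospholipase Plcb3 (0.39, SE 0.092), Mid1ip1 (0.38, SE 0.088), which promotes lipogenesis, and Ctc1 (0.32, SE 0.072). Lower were the GTPase Rras2 (-0.63, SE 0.125), Ptges3 (-0.47, SE 0.086), Fam133b (-0.44, SE 0.078), the cap methylation subunit Fam103a1 (-0.39, SE 0.075), Ing3 (-0.35, SE 0.069) and Ufm1 (-0.31, SE 0.061). Limma called 268 genes, 58 higher and 210 lower, with 2655 at an unadjusted p under 0.05. With libraries scaled to the median log2 ratio the split was 45 higher and 69 lower. The panel genes did not pass: Csf1r was at 1010 ± 116 against 804 ± 109 FPKM (0.33, SE 0.097, adjusted p = 0.0616). The log2 differences were -0.24 (SE 0.153) for Bdnf, 0.11 (SE 0.081) for Dlg4, 0.02 (SE 0.091) for Syp, 0.27 (SE 0.530) for Cx3cr1, 0.04 (SE 0.240) for P2ry12, 0.23 (SE 0.108) for Tmem119, 0.19 (SE 0.217) for Oxtr, 0.39 (SE 0.214) for Fos and 0.85 (SE 1.57) for Ttr.

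Of the 23 SREBP targets 4 rose in HFD-F against HFD-C (7 adjusted over the list alone), Dhcr7 (0.28, SE 0.075) included, with a median of 0.18 (adjusted p = 2.91e-06 at the preset correlation, adjusted p = 0.392 with an estimated correlation). Of 19 glucocorticoid response genes Sgk1 fell (5 adjusted over the list alone; median -0.29, adjusted p = 0.000406, and adjusted p = 0.392 with an estimated correlation). With the GC trend removed, 1 SREBP target was called higher and 0 glucocorticoid response genes lower, while the list medians were 0.22 (adjusted p = 2.02e-09, and adjusted p = 0.189 with an estimated correlation) and -0.28 (adjusted p = 2.21e-06, and adjusted p = 0.156 with an estimated correlation). Heat shock genes had a median of -0.18 with 0 members called by limma (adjusted p = 0.0119, and adjusted p = 0.827 with an estimated correlation). Vascular and border lists lay higher: fibroblast (median 0.86 over 11; 7 adjusted over the list alone; adjusted p = 1.36e-06), endothelial (0.39 over 10; 7 adjusted over the list alone; 0.000257) and pericyte genes (0.37 over 8; 4 adjusted over the list alone; 0.0108). Of the last, Vtn (0.49, SE 0.134) was called over all genes, but 0 pericyte genes were called with the GC trend removed. Each of these 3 lists had an adjusted p = 0.392 with an estimated correlation. Complement genes (0.22 over 18; 1 adjusted over the list alone; 0.0057, with adjusted p = 0.392 with an estimated correlation), microglia (0.22 over 20; 3 adjusted over the list alone; 0.000831), MHC (0.33 over 12; 0.0229) and hypothalamus genes (0.43 over 7; 1 adjusted over the list alone; 0.029) lay higher as well, the last 3 with an adjusted p = 0.474 with an estimated correlation. So did border macrophage (0.54 over 5; 0.0229, and adjusted p = 0.486 with an estimated correlation) and striatum genes (0.32 over 12; 0.0486, and adjusted p = 0.827 with an estimated correlation). Outside the lists past the preset correlation, Nfkbia (-0.58, SE 0.125) and Hdac2 (-0.28, SE 0.069) fell. With the GC trend removed Nfkbia still passed (-0.62) and Hdac2 did not.

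The differences between HFD-F and HFD-C followed transcript GC (Spearman 0.473 over 13761 genes), and 14 genes were called with the GC trend removed, of which 12 were among the 260 called before. They included Srebf1 (0.40), Fads2 (0.40), Rab3il1 (0.42), Ncbp2 (-0.29), Rras2 (-0.55) and Nfkbia (-0.62). The count was 109, 138, 102, 107 and 129 without HFD-C libraries 1, 2, 4, 6 and 9, and 113, 72, 106 and 158 without HFD-F libraries 3, 4, 6 and 7. It was 8 within the 3 title prefixes that both groups share (7 higher, 1 lower), 0 with means per prefix and 40 with the first digit of the prefix in the model (7 higher, 33 lower). It rose to 1077 with library weights and 524 without the libraries apart on the first principal component.

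Genes changed with offspring code F moved the same way under both maternal codes, in comparisons that share no library. Of the genes called in both, 37 were higher in both, 187 lower in both and 0 opposite, where independent lists would share 2.63 and 18.6. Across 16029 genes the changes correlated at 0.477, and with the GC trend removed at 0.382, where 3 were called higher in both and 8 lower in both. The test of the difference itself, the interaction of offspring and maternal code, gave 0 genes with limma and 441 at an unadjusted p under 0.05. Rad17 (0.41, SE 0.103) and Zfp966 (0.79, SE 0.216) had the smallest p, followed by the liver genes Serpina1d, Serpina3k and Mup13, all at an adjusted p of 1. For FFD-C minus HFD-C against FD-C minus CD-C, limma also gave 0 genes and 617 at an unadjusted p under 0.05. Ing2 (0.38, SE 0.089), Rchy1 (0.76, SE 0.186), the sodium channel Scn8a (-1.32, SE 0.337), Myc (-0.48, SE 0.125) and Srsf3 (0.55, SE 0.143; 2 rows) had the smallest p, at an adjusted p of 0.997.

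**Figure D3:**
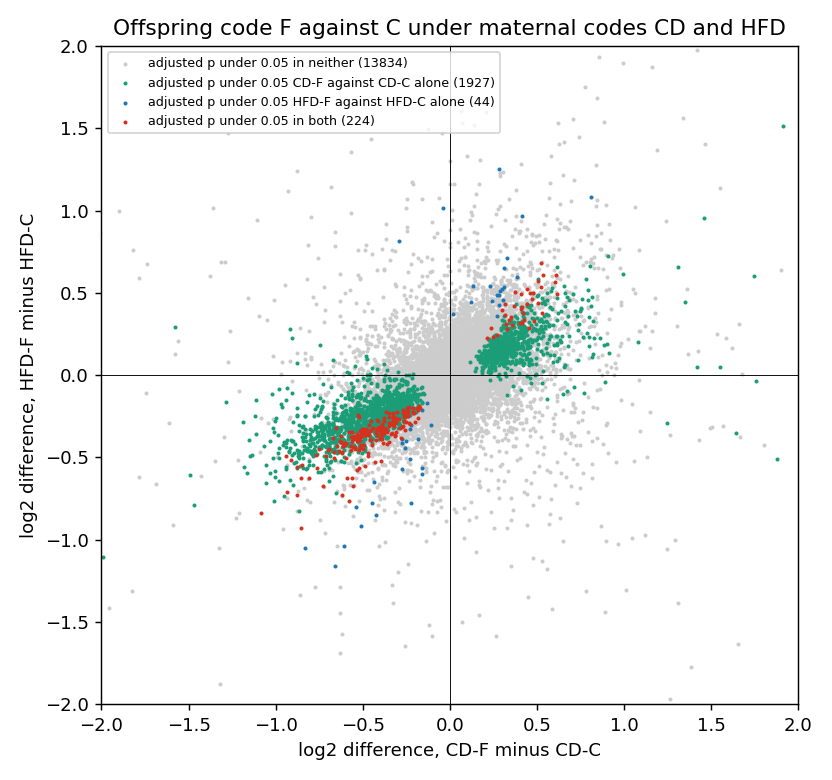
Log2 difference of CD-F from CD-C (x axis) and of HFD-F from HFD-C (y axis) for 16029 genes, 1 point each, with 44 genes beyond the axis limit of 2 not drawn. Colours mark 1927 genes with an adjusted p under 0.05 in the former alone, 44 in the latter alone, 224 in both and 13834 in neither, and the 224 lie in the lower left and upper right of the plot.

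Against the CD-C reference, FFD-C differed in 1 gene, the signal peptidase subunit gene Spcs3, which fell (17.2 ± 3.54 against 68.5 ± 20 FPKM, n = 8 each; log2 -1.88, SE 0.285, adjusted p = 0.00064 with limma) and was named as the sole call, after its values were seen. Its row takes 2 separate levels across the libraries, and the lower level held 8 libraries of FFD-C, 5 of HFD-C, 1 of CD-C and 0 of the other groups. The spread was wide in HFD-C as well (44.0 ± 32.1 FPKM), and 528 genes had an unadjusted p under 0.05. With means per title prefix, and without the 4 CD-C libraries that held Alb, limma called 0 genes, with 488 and 375 at an unadjusted p under 0.05. Dentate granule cell genes had a median of -0.50 over 12 (adjusted p = 4.13e-07), choroid plexus -0.87 over 13 (0.0178), fibroblast -0.33 over 11 (0.0178), heat shock -0.12 over 20 (0.0243) and ribosomal protein 0.07 over 29 (0.0178), with 0 members called and an adjusted p = 0.92 with an estimated correlation for each. HFD-F differed from CD-C in 432 genes, 96 higher and 336 lower, and in 220 with the GC trend removed. The count was 101 with the first digit of the title prefix in the model and 81 with the GC trend removed and a random prefix block. With means per title prefix limma called 0 genes, with 1790 at an unadjusted p under 0.05. Its SREBP targets had a median of 0.27 with 5 of 23 higher (12 adjusted over the list alone; adjusted p = 9.26e-11, and adjusted p = 0.202 with an estimated correlation). Heat shock genes had a median of -0.38 with 2 of 20 lower (11 adjusted over the list alone; 1.3e-07, and adjusted p = 0.415 with an estimated correlation), and glucocorticoid response genes -0.29 with 3 of 19 lower (7 adjusted over the list alone; 0.000277, and adjusted p = 0.313 with an estimated correlation). Scaled to the median log2 ratio, the split was 179 higher and 192 lower, and without the 4 CD-C libraries that held Alb the count was 77.

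**Figure D4:**
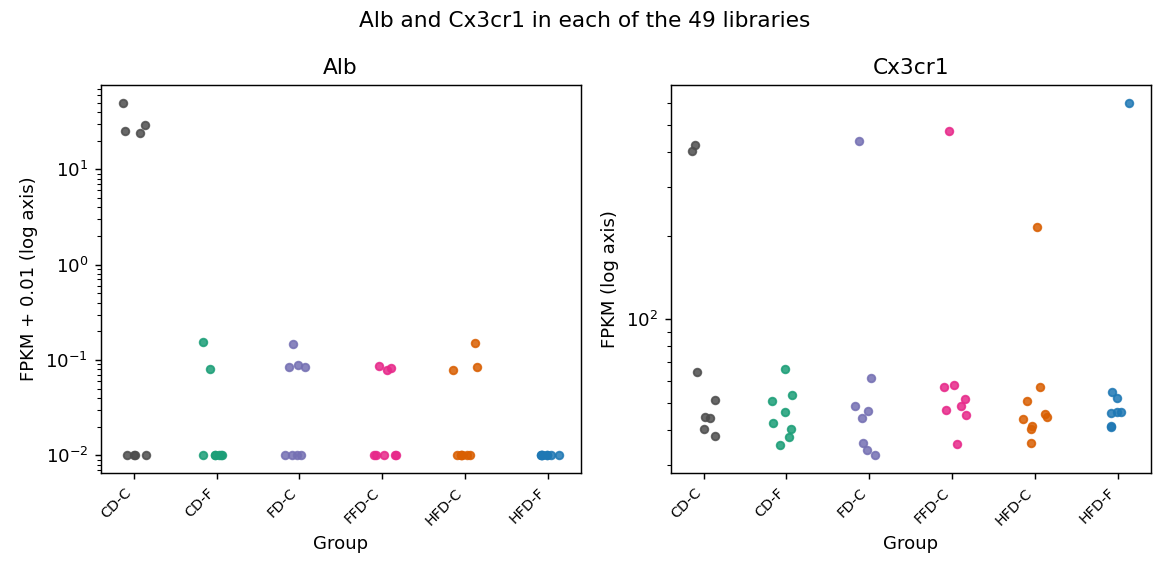
FPKM of Alb (left, with 0.01 added) and Cx3cr1 (right) in each of the 49 libraries by group (x axes), on log y axes. Alb stands at 24.3 to 50.1 FPKM in 4 CD-C libraries and at or below 0.145 in the other 45, and Cx3cr1 at 215 to 602 in 6 libraries of 5 groups and at 32.4 to 66.5 in the rest.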

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

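The test of title prefix differences, that of adipose tissue and that of a difference between the 6 groups in rows with 2 levels were written before their results were seen, and the other tests of this part, the counts of splits included, were chosen after the result was seen.

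Single libraries stood far from the rest of their group for 10 of the 96 sets of values examined (panel genes, column sums, mitochondrial share and GC slope by group), where chance gives about 4.8. The fractalkine receptor gene Cx3cr1, a marker of microglia, was high in FD-C replicate 8 (439 FPKM, next 61.3), FFD-C replicate 5 (476, next 57.9), HFD-C replicate 6 (215, next 57.1) and HFD-F replicate 5 (602, next 54.9). Other microglial genes stood apart in other libraries: P2ry12 was low in HFD-C replicate 2 (12.3, next 37.3), Tmem119 high in CD-C replicate 3 (7.30, next 5.28) and CD-F replicate 8 (9.26, next 6.09), Csf1r high in FFD-C replicate 1 (1060, next 784) and Aif1, on 4 rows, high in HFD-F replicate 8 (3.28, next 2.05). The activity-regulated gene Arc was low in HFD-F replicate 3 (58.7, next 115).

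Some lists differed between groups when the difference itself was tested at the preset correlation, though no single gene did. The F change of myelin genes was lower under maternal code HFD than under CD (median difference -0.40, adjusted p = 0.0015, and 0.982 with an estimated correlation). Those of fibroblast (0.77, 1.22e-06), border macrophage (0.72, 0.0015) and heat shock genes (0.30, 1.22e-06) were higher, each at 0.883 with an estimated correlation. The difference of FFD-C from HFD-C exceeded that of FD-C from CD-C for ribosomal protein (0.25, 2.61e-08), respiratory chain (0.24, 7.24e-07) and heat shock genes (0.21, 0.00976). It was lower for presynaptic genes (-0.15, 0.00081), the excitatory postsynapse (-0.12, 0.000872), autism-associated genes (-0.12, 0.00621) and oligodendrocyte precursor genes (-0.16, 0.0109), and all 7 stood at 0.892 with an estimated correlation. Across 13761 genes the difference of FFD-C from HFD-C followed transcript length (Spearman -0.453), while that of FD-C from CD-C hardly did (-0.018). Whether these 7 list differences follow transcript length was not tested.

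Each count of changed genes was set against 100 splits of the same libraries into groups of the same sizes, the real one included. As many genes as the real count were called in 1 split for FD-C against CD-C (32 real, 1 the highest other), 1 for CD-F against CD-C (2151, 1608), 1 for HFD-F against HFD-C (268, 1) and 1 for HFD-F against CD-C (432, 39). Chance is argued against for these if single libraries are exchangeable, but 1 of 100 is the smallest share possible and the number of comparisons was not corrected for. For FD-C against CD-C the case is weaker. There 5 of 100 splits, the real one included, had as many genes at an unadjusted p under 0.05 (1529 real, 2250 the highest other). Its count of calls also fell to 1 without the CD-C libraries that held Alb, and to 1 without FD-C library 3. For XX against XY 2 splits called as many (18, 154). That count holds the sex-linked genes that the marks imply, so chance is not excluded for its autosomal genes. The splits ignore title prefixes, and with means per prefix 0 genes were called in FD-C against CD-C, HFD-F against HFD-C and HFD-F against CD-C, so chance among prefixes is not excluded for these 3. In CD-F against CD-C 881 were called, but whole prefixes were not regrouped, so chance among prefixes is not excluded there either. The split of the CD-F and CD-C libraries that called 1608 genes left 14 of the 16 libraries with their real grouping, so the groups themselves can account for it. Apart from the real grouping, 14 splits of these libraries called any gene and 2 called over 100, that of 1608 among them. The remaining split of these 2 kept fewer libraries in their real grouping, and its cause was not tested. The split of the XX and XY libraries that called 154, against 18 real, left 33 of the 49 libraries with their real grouping, and its cause was not tested. Chance cannot be excluded for the count of FFD-C against CD-C, where 14 splits did as well (1 real, 2 the highest other). A count ignores the strength of a call, and the levels of the gene called, Spcs3, did differ among the 6 groups (adjusted permutation p = 0.0195). The other 5 comparisons had no count to test beyond 0, which all 100 splits reach by construction: HFD-C against CD-C (highest other 1), FFD-C against HFD-C (2), offspring code F by maternal code (2), the maternal codes FFD and FD (1) and the XX or XY mark by HFD-C against CD-C (7).

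The changes with offspring code F, from Srebf1 to Hspa5, ran along transcript GC and partly along title prefixes, and a GC trend of technical origin was set against an effect of the code. With the trend removed, 776 genes were called in CD-F against CD-C (2 of 100 splits as many, highest other 949) and 14 in HFD-F against HFD-C (1 of 100, highest other 2). The correlation of both F changes, from means balanced for the mark, was then 0.381 (highest other split 0.277). Mean GC slopes differed by group, at 0.159 in CD-F, -0.0739 in CD-C, 0.0267 in HFD-F and -0.126 in HFD-C. A remainder that the removal missed would therefore also follow the labels. The trend as the whole cause is argued against only if its removal was complete. It stays open as a partial cause: the median log2 change of the genes called lower went from -0.45 (SE 0.110) to -0.23 (SE 0.097) in CD-F and from -0.36 (SE 0.086) to -0.20 (SE 0.084) in HFD-F, where the fold shrank more than the error; the genes called higher went from 0.34 (SE 0.098) to 0.25 (SE 0.090) in CD-F and from 0.45 (SE 0.109) to 0.38 (SE 0.103) in HFD-F, where 5 of 57 were still called although most of the fold stayed. Prefix differences as the whole cause of the shared direction are argued against, in the HFD groups alone, by the 3 prefixes that hold both. There the CD-F calls moved the same way within prefix by a mean of 0.175 (89.8% of 2151 genes, 1 of 45 orders, highest other 0.145). This rests on 3 HFD-C and 8 HFD-F libraries, which carry opposite XX or XY marks in each of these prefixes, and 1 of 45 is the smallest share possible. For the genes called in CD-F against CD-C, where no prefix is shared, prefix differences stay open. For FD-C against CD-C, 0 genes were called with the trend removed (highest other split 1) and the 31 lower genes with a GC value went from -0.39 (SE 0.085) to -0.25 (SE 0.086), but a count of 0 is reached by all 100 splits and decides nothing, so the trend and an effect of the maternal code both stay open.

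Liver transcripts such as Alb, the main plasma protein, and Cyp2e1 were present in CD-C replicates 2, 5, 7 and 8 at 24.3, 29.2, 50.1 and 25.5 FPKM of Alb and 48.3 to 66.9 of Cyp2e1, and in the other 45 libraries at no more than 0.145 and 5.32, and Fabp4, a gene of adipocytes and vessels, went with them at 5.37 to 6.85 against no more than 2.37. An effect shared by all CD-C libraries is argued against by the 4 CD-C libraries under 1 FPKM of Alb, and title prefix as the source by 2 prefixes with libraries of both kinds. RNA or reads from liver may be the source, since in 37 of 60 liver genes all 4 libraries stood above the other 45, but this cannot be told apart from other sources: the first 30 genes listed (26 above) had left out genes already seen not to differ, and the 30 added for that reason gave 11. Of 5 liver genes checked for abundance, Apoa1 (0.587 to 0.959 FPKM), Apoc3 (0.0504 to 0.0939), Orm1 (0.0214 to 0.0491), Cyp3a11 (0.0139 to 0.0876) and Cyp2c29 (0.022 to 0.141) were all under 1 FPKM in the 4 libraries, and 13 of the 60 reach 1 FPKM in the median of the other 45. Adipose tissue as a source cannot be told apart either, since all 4 libraries stood above the other 45 in 2 of 9 adipocyte genes other than Fabp4, and no biological explanation was tested.

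Rows that switch between 2 separate levels, Cx3cr1 among other genes, made up 195 of the 10752 rows with a mean of at least 5 FPKM, and 122 of them share their symbol with another row (62.6% against 6.8% of all). Reads of a symbol placed on different rows are consistent with this, since in these 122 summing the rows of a symbol left 17.6% of the high-to-low log2 difference, while the other 73, Cx3cr1 and Spcs3 among them, stay open. A difference between the 6 groups is argued against, as 0.51% of these rows differed among groups, which is 1 row, that of Spcs3 (adjusted permutation p = 0.0195); single rows among the 50 with fewer than 5 libraries at the rarer level could hardly pass, but of the other 145 it was also 1, and 14 of the 195 had an unadjusted permutation p under 0.05 where chance gives 9.75. A larger share of microglia in the 6 libraries with 215 to 602 FPKM of Cx3cr1 is argued against by the other 19 homeostatic markers, which differed by a median of -0.122 where Cx3cr1 differed by 3.15. The source of the high level of Cx3cr1 itself stays open.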

How the results depend on the processing

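Alternatives chosen after the result was seen were the removal of GC or length trends, Ttr as a covariate, means per prefix, rows summed by symbol, rows with a GC value alone, and the sets without the Alb libraries or those apart on the first principal component. For every value given below the cause was not tested, except where fewer libraries or genes entered.

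The genes changed in CD-F against CD-C, Srebf1 and Hspa5 included, were 2151 and stayed between 1904 and 2736 under pseudocounts, filters, scaling, covariates, a random prefix block and the set without the libraries apart on the first principal component. They came to 4004 with library weights, 1426 with the groups compared alone, 881 with means per prefix, 1234 without the Alb libraries, 776 with the GC trend removed, 976 with length as well and 646 with the GC trend removed and a random prefix block. Leaving out single libraries gave 1558 to 2596.

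Those of HFD-F against HFD-C, such as Srebf1 and Ncbp2, were 268. They came to 140 without a filter, 114 with median scaling, 167 with a random prefix block, 40 with the first digit of the prefix, 1077 with library weights, 8 within shared prefixes, 0 with means per prefix, 14 with the GC trend removed, 59 with length as well, 7 with the GC trend removed and a prefix block, 175 without the Alb libraries and 524 without those apart on the first component. Leaving out single libraries gave 72 to 372: 109, 138, 102, 107 and 129 without HFD-C 1, 2, 4, 6 and 9, and 113, 72, 106 and 158 without HFD-F 3, 4, 6 and 7.

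Those of FD-C against CD-C, Nck1 among them, were 32. They came to 78 without a filter, 7 with median scaling, 8 with quantile normalization, 19 without a covariate, 13 with a random prefix block, 15 with the first digit of the prefix, 283 with library weights, 1 with the groups compared alone, 18 with Ttr, 0 with means per prefix, 0 with the GC trend removed, 2 with length as well, 0 with the GC trend removed and a prefix block, 1 without the Alb libraries and 91 without those apart on the first component. Median scaling split them into 1 higher and 6 lower, where 1 and 31 had been called. Leaving out single libraries gave 1 to 77: 16, 7, 13, 13, 7, 2 and 9 without CD-C 1, 2, 3, 4, 5, 7 and 8, and 8, 20, 1, 7, 77, 3, 5 and 20 without FD-C 1 to 8 in that order.

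HFD-F against CD-C, 432 genes, came to 287 with a random prefix block, 101 with the first digit, 1715 with library weights, 0 with means per prefix, 220 with the GC trend removed, 249 with length as well, 81 with the GC trend removed and a prefix block, 77 without the Alb libraries and 1125 without those apart on the first component. FFD-C against CD-C, Spcs3 alone, came to 3 without a filter, 2 with library weights, 0 with means per prefix and 0 without the Alb libraries. HFD-C against CD-C, 0 genes with limma and 379 at an unadjusted p under 0.05, came to 26 without a filter and 5 with library weights, and to 0 to 5 without single libraries, with 5 without CD-C 1, 3, 4 or 6. FFD-C against HFD-C kept 0 without each library. Both interactions kept 0 under the alternatives run, and XX against XY gave 14 to 26.

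List calls at the preset correlation became 0 with an estimated correlation in HFD-C against CD-C, FFD-C against HFD-C, FD-C against CD-C, CD-F against CD-C, HFD-F against HFD-C, FFD-C against CD-C and HFD-F against CD-C, and 0 in each with the GC trend removed and an estimated correlation. With GC and length trends removed there were 1 in FFD-C against HFD-C, 3 in FD-C against CD-C and 5 in CD-F against CD-C, and with a random prefix block 3 in FD-C against CD-C. The split correlation of HFD-C from CD-C with FFD-C from HFD-C was -0.011 and came to -0.187 over genes with any difference among groups (57 of 100 draws without an effect as low) and 0.048 with GC and length trends removed, and that with HFD-F from HFD-C was 0.071 and came to 0.107 and 0.105.

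Many named genes lost their call under some alternatives. Of 88 in CD-F against CD-C, 49 did so with means per prefix, 48 with the GC trend removed, 47 with length as well, 50 with the GC trend removed and a prefix block, 30 without the Alb libraries, 27 with the groups compared alone and 23 without a filter, and single libraries left out took 239 of 1408 values. Of 39 in HFD-F against HFD-C, 26 did so with means per prefix, 26 within shared prefixes, 20 with the GC trend removed and 13 with the first digit of the prefix. Of 15 in FD-C against CD-C, 10 did so with means per prefix, 10 with the GC trend removed and 8 without the Alb libraries. Of 7566 values of 212 named gene results, 4 values, of 3 results that had passed, lost their direction. Igf1 in CD-F against CD-C, a fall in 5 of 8 libraries, stood at 0.001 with the GC trend removed and at 0.001 with a prefix block as well. Serpina1d and Serpina3k in FD-C against CD-C came to 0 and 0 without the Alb libraries, by the removal of those that held them. Another 133 sign changes were of genes that had not passed. Without read counts the limit that depth sets on low genes cannot be given.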

Other observations

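All tests of list scores in this part were chosen after the result was seen.

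Genes of adult neurogenesis, such as Sox11 and Neurod1, had a lower mean score in CD-F than in CD-C with the GC trend removed, -0.27 ± 0.334 against 0.23 ± 0.185 (difference -0.50, 5 of 8 CD-F libraries below all of CD-C, adjusted p = 0.0457 by exact permutation). As a list these genes did not pass on the same values (adjusted p = 0.0623 at the preset correlation, 0.274 with an estimated correlation), and the score did not pass in the deposited values (0.0933) or for HFD-F against HFD-C (0.442). Complement and engulfment genes, such as Cd68, had a higher score in HFD-F than in HFD-C, 0.32 ± 0.265 against -0.16 ± 0.195 (difference 0.48, 6 of 8 above all of HFD-C, adjusted p = 0.0219 by exact permutation), again not in the deposited values (0.0587) or for CD-F against CD-C (0.198). As a list they had an adjusted p = 0.0102 at the preset correlation, but 0.232 with an estimated correlation. Other lists moved with complement in HFD-F with the trend removed, without passing: microglia by 0.61 (adjusted p = 0.198 by exact permutation), endothelial genes by 0.96 (0.0653), pericyte genes by 0.78 (0.0653) and fibroblast genes by 1.18 (0.0903). The complement change is therefore not shown to be specific. Whether these differ between maternal codes was not tested on the scores. With the trend removed 3 of 42 lists passed in CD-F against CD-C and 1 in HFD-F against HFD-C, against 2 and 0 in the deposited values, and the other 3 comparisons gave 0.

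Transcripts of SREBP targets in the hippocampus may rise with offspring code F beyond the GC trend. Sterols themselves were not measured. Over the SREBP target list, with Srebf1 and Dhcr7, the score in CD-F was 0.64 ± 0.341 against -0.43 ± 0.31 in CD-C (difference 1.07), with 8 of 8 CD-F libraries above all of CD-C and an exact permutation p of 0.000155, the smallest that 12870 regroupings can give (adjusted p = 0.0131 over 84 tests). For HFD-F against HFD-C the difference was 0.81 with 1 of 8 libraries above all of HFD-C and an adjusted p = 0.0952 by exact permutation. The rise therefore stays a hypothesis, with a difference beyond the fitted trend under maternal code CD in the data that gave rise to it. Under HFD it stays open. With an estimated correlation the list did not pass in either (adjusted p = 0.274 and 0.189). Title prefixes, which CD-C and CD-F do not share, stay an open alternative for the former.

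Chaperone expression may fall with offspring code F beyond the same trend. Heat shock and unfolded protein genes, with Hspa5, Hsp90aa1 and Creld2, scored -0.67 ± 0.528 in CD-F against 0.54 ± 0.472 in CD-C (difference -1.21, 7 of 8 below all of CD-C, exact permutation p = 0.000622, adjusted p = 0.0219), and differed by -0.45 for HFD-F against HFD-C (1 of 8 below, adjusted p = 0.442 by exact permutation). With an estimated correlation the list did not pass in either (adjusted p = 0.274 and 0.555), and title prefixes stay an open alternative for CD-F here too. Groups with offspring code C also lay lower than CD-C on this list at the preset correlation, HFD-C by a median of -0.15 (adjusted p = 4.18e-06), FD-C by -0.17 (0.0234) and FFD-C by -0.11 (0.022), none with an estimated correlation, so part of the difference may lie in CD-C. Glucocorticoid response genes, with Sgk1 and Tsc22d3, were taken up for the same question, and their scores differed by -0.52 (6 of 8 below, adjusted p = 0.0653 by exact permutation) and -0.66 (4 of 8 below, 0.119), which leaves that hypothesis undecided. A stress of dissection or handling that differed between groups was not tested.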
